A study of Homo sapiens with 10 samples.

How the data were processed

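RNA from 10 samples of 12Z cells, grown in serum, starved overnight in charcoal-stripped serum, pre-treated with DMSO or inhibitor and then exposed to IL1β or left without it, was sequenced after poly(A) enrichment. Per the labels there were 5 groups of 2 samples: vehicle, IL1β, and IL1β with 1 µM CDD-2728, 10 µM CDD-2728 or 1 µM CDD-3013. Per the submitters' processing notes, fastp, STAR, featureCounts and the build hg38 were used; their versions and settings are not given in the sources used here. The authors deposited 1 table of gene counts, whole numbers of reads per gene ID and library, and these deposited counts were the input of every fit. Total counts were 19479416 and 17810555 (vehicle), 18166317 and 16312600 (IL1β), 18453896 and 16517549 (1 µM CDD-2728), 18261624 and 16474440 (10 µM CDD-2728) and 17971191 and 17248542 (CDD-3013). All columns were used, and no 2 columns were identical.

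The table held 62750 gene IDs. Of these, 61918 matched a reference list of gene symbols with their version, 754 matched without it and 78 did not match. Gene coordinates and types came from the GENCODE 29 annotation of GRCh38, which held 58305 of the IDs. Where 2 IDs had 1 symbol, the symbol went to the ID with more reads (1480 IDs were set aside in this way for naming). Transcript length and GC content were taken from GENCODE 29 as well, for 15317 (97.3%) of the tested genes.

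Counts were filtered with filterByExpr (minimum count 10, by group), scaled with TMM factors (0.9174 to 1.1139) and fitted in edgeR 4.0.16 with the quasi-likelihood method (robust, 5 residual degrees of freedom, all 10 libraries in 1 fit) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over the 15740 tested genes in each comparison, with a threshold of 0.05. SEs of log2 fold changes are Wald values from the fitted quasi-likelihood variance, taken as not below counting error. The 6 comparisons were IL1β against vehicle, each of the 3 inhibitor arms against IL1β, 10 against 1 µM CDD-2728, and CDD-3013 against CDD-2728 at 1 µM. The common biological coefficient of variation was 0.06, and the chi-square per degree of freedom of replicate counts under counting error alone was 4.69, 2.52, 7.46, 3.82 and 5.65 in the order of the groups above. Pearson correlations of log2 CPM between replicates were 0.9864 to 0.9884. All genes of the mitochondrial genome together held 3.19% to 3.71% of counts, 82 ribosomal protein genes 2.81% to 4.75%, and the 20 largest genes 7.81% to 8.85%. Principal components used the 500 most variable genes, with a prior count of 2.

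A total of 33 gene lists were fixed by name before the data were examined, as were the comparisons, the main test and the rule for named genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1, with the preset correlation of 0.01 and with an estimated one, and adjusted over the lists of each comparison. The immune marker list, with 3 tested members, was not tested. Genes are named by a rule with several parts. In IL1β against vehicle and the 3 inhibitor arms it takes the 8 largest changes in each direction, and in the other 2 comparisons the 5 largest. These come from called genes with a mean CPM of at least 2 in the higher group and both libraries of 1 group beyond both of the other, leaving out clone names, antisense genes and pseudogenes. It adds up to 4 members of each list with the smallest adjusted p in a comparison, and the 3 JNK genes MAPK8, MAPK9 and MAPK10. Opposite effects of the doses of CDD-2728 were looked for only among genes named by the rule and among the lists, not among all tested genes. Always named, where tested, are 21 genes: CXCL8, IL6, CCL2, PTGS2, MMP1, MMP3, MMP10, LIF, CSF2, ICAM1, VCAM1, NFKBIA, TNFAIP3, SOD2, JUN, JUNB, FOS, FOSL1, ATF3, DUSP1 and EGR1. The text gives part of the genes this rule takes. CSF2 had too few counts to be tested. Fold changes of genes near 0 counts are given as exact ratios with 95% counting intervals, or as at least so many fold, with 3 counts taken as the upper bound of a group at 0.

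The share of the IL1β response left was, for genes called and changed at least 2-fold by IL1β, the log2 difference of each arm from vehicle over that of IL1β. Because the arms share the IL1β libraries, 20 simulations of arms with no effect (seed 7) were run for the shares and for the overlaps of calls.

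Alternatives tried were size factors by relative log expression, library totals, no filter and a stricter filter (CPM of at least 5 in at least 2 libraries), DESeq2 1.42.0, fits of only the 4 libraries compared, an added replicate number, other minima of the IL1β response, IL1β libraries split between choosing and measuring genes, and leaving out each library in turn. A correction for transcript length and GC content was added after seeing the data: smooth trends of log2 CPM per library over length and over GC content (loess, span 0.3, 2 rounds) were entered as offsets of the edgeR fit. A test of a few genes taking most of the counts as the source of the length trend was planned and not run, since a constant factor per library cannot change a rank correlation.

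The steps were tested on simulated data made for CDD-3013 against IL1β (14985 genes). Of 50 changed genes at each size, edgeR called 42% at 1.3-fold, 76% at 1.5-fold, 90% at 2-fold and 94% at 4-fold. Of 14765 unchanged genes edgeR called 12 and DESeq2 4, and camera called 0 of 20 unchanged lists. Simulated genes varied independently of each other, so the camera result does not cover lists whose genes vary together. A simulated length and GC trend alone gave 3161 calls for CDD-3013 against IL1β and 1543 for CDD-3013 against CDD-2728, and 0 in each after the correction. That trend was the one the correction itself estimates, so the 0 shows only that a trend of this form is removed. Whether the correction spares true changes was not tested. True shares of 0.5 and 1 of the response came out as 0.493 and 0.997, for genes all raised 4-fold. That setting held no response genes near the 2-fold minimum, of low level or lowered by IL1β. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the tables and figures.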

Results

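Poly(A) RNA was profiled in 12Z cells, an established immortalized line of human endometriotic epithelial cells from peritoneal lesions. Serum-starved cells received vehicle (DMSO), CDD-2728 (1 or 10 µM) or CDD-3013 (1 µM), compounds described as inhibitors of the kinase JNK, and then IL1β for 6 h. The vehicle group received no IL1β, and no group received an inhibitor alone. The 5 groups held 2 libraries each (n = 2), with 16312600 to 19479416 counts per library. A total of 15740 genes were tested. Levels are CPM (counts scaled to the size of the library), mean ± SD of 2 libraries, and log2 fold changes carry ± SE. The p-values measure the spread between samples, which may be technical, since nothing states that the 2 samples of a group were separate cultures.

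The cells carried the epithelial keratin KRT8, the fibrillar collagen COL1A1 and the mesothelial marker LRRN4 at high levels, with means over the 10 libraries of 6770, 2800 and 464 CPM. Each was the most abundant of its marker list. A mean under 1 CPM was found for 3 of 12 epithelial, 2 of 14 endometrial stromal and 1 of 8 mesothelial markers. Medians of the epithelial, endometrial stromal and mesothelial marker lists ranged over the groups from 6.06 to 9.76, 32.75 to 47.19 and 39.33 to 44.23 CPM. Endothelial markers had medians of 0.46 to 0.75 CPM, with the receptor KDR the most abundant at a mean of 28.2 CPM. Of 17 immune cell markers, 15 had a mean under 1 CPM over the libraries, and the monocyte receptor CD14 was the most abundant at a mean of 18.9 CPM. The first 3 principal components held 70.4%, 14.9% and 4.6% of the variance. The first set both vehicle libraries (47.87 and 48.09) apart from all others (-15.5 to -6.93), and the second set 10 µM CDD-2728 (21.43 and 21.44) apart.

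Of the gene lists tested, those of chemokines and cytokines and of NF-κB pathway and feedback genes had the largest median rises under IL1β. The neutrophil attractant CXCL8 went from 1.931 ± 0.272 to 960 ± 64.2 CPM (chr4:73740506-73743716, plus strand, GRCh38), a log2 change of 8.95 ± 0.26 (edgeR quasi-likelihood test, adjusted p = 2.34e-13). The acute-phase cytokine IL6 rose from 0.1204 ± 0.0256 to 78 ± 9.25 CPM (chr7:22725884-22732002, plus strand; log2 change 9.25 ± 0.65). The monocyte attractant CCL2 rose from 1.866 ± 0.0367 to 328.7 ± 11.4 CPM (chr17:34255218-34257203, plus strand; 7.45 ± 0.18). PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, rose from 0.5482 ± 0.269 to 45.85 ± 1.06 CPM (chr1:186671791-186680427, minus strand; 6.34 ± 0.34). SAA1, an acute-phase apolipoprotein, rose 85.5-fold, to 58.67 ± 3.04 CPM (chr11:18266174-18269977, plus strand). The mitochondrial superoxide dismutase SOD2 rose 36.9-fold, and the adhesion molecules ICAM1 and VCAM1 8.81- and 12.5-fold. For genes near 0 in vehicle, the chemokine CCL20 was at least 128-fold and the lipolysis regulator G0S2 at least 46.8-fold higher, CSF3 1340-fold (240 to 53000) and SAA2 391-fold (133 to 1900). Such floors and intervals cover counting error only.

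By list, all 26 tested chemokines and cytokines rose under IL1β (26 higher and 0 lower when adjusted over the list alone; median log2 change 4.89, or 4.75 with genes near 0 counts set to their bounds; camera adjusted p = 5.64e-127). Of 26 NF-κB pathway and feedback genes 24 rose and 0 fell (25 and 0 adjusted over the list alone, median 2.18, camera adjusted p = 2.37e-118). The inhibitor NFKBIA (2.44 ± 0.08) and the ubiquitin-editing enzyme TNFAIP3 (4.72 ± 0.08) were among them. Of 37 interferon-stimulated genes 34 rose and 0 fell (34 and 0 adjusted over the list alone, median 1.1, camera adjusted p = 6.31e-28). They included the antiviral GTPase MX1 (5.53-fold) and the guanylate-binding GBP1 (6.28-fold). Adhesion molecules and surface receptors gave 22 higher and 3 lower of 30 (23 and 4 adjusted over the list alone, median 0.85, camera adjusted p = 7.96e-27). Matrix proteases and inhibitors gave 14 higher and 4 lower of 27 (16 and 5 adjusted over the list alone, median 0.55, camera adjusted p = 1.42e-06). In that list the collagenase MMP1 (2.8-fold) and the stromelysin MMP3 (18.6-fold) rose, as did the serpin SERPINB2 (56.4-fold), which is not in it.

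The AP-1 family gave 11 higher and 1 lower of 16 genes under IL1β (12 and 1 adjusted over the list alone, median 0.54, camera adjusted p = 3.4e-10). JUN, the AP-1 subunit that JNK phosphorylates, rose from 139.3 ± 9.44 to 316.4 ± 11.7 CPM (chr1:58780788-58784327, minus strand; 1.18 ± 0.07), and JUNB, FOSL1 and ATF3 rose 3.41-, 2.92- and 2.62-fold. FOS did not pass the test (-0.22 ± 0.26). The early growth response factor EGR1 fell by 1.97 ± 0.27 on the log2 scale, although 12 of 20 immediate-early and SRF target genes rose and 4 fell (12 and 4 adjusted over the list alone, median 0.49, camera adjusted p = 0.000226, and adjusted p = 0.127 with an estimated correlation). HBEGF, a ligand of the EGF receptor, rose from 51.41 ± 4.5 to 152.7 ± 3.21 CPM (chr5:140332843-140346631, minus strand). CREB5, a bZIP transcription factor, rose from 3.266 ± 0.442 to 17.75 ± 1.45 CPM (chr7:28299321-28825894, plus strand).

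Genes lower under IL1β included the synaptic organizer CBLN2 (28.1-fold), FAM13C (26.4-fold), the transcription factors DACH1 (10.4-fold) and FOXP2 (10.3-fold), MAP2K6, a kinase that activates p38 (9.59-fold), the circadian factor DBP (7.88-fold), the pro-apoptotic BMF (3.96-fold) and SMAD6, an inhibitor of BMP signalling (3.77-fold). The stromal marker list gave 2 higher and 5 lower of 12 (2 and 6 adjusted over the list alone, median -0.18, camera adjusted p = 0.0411, and adjusted p = 0.127 with an estimated correlation). In it the decidual transcription factor HAND2 fell by 1.04 ± 0.1 and the receptor PDGFRB by 1.26 ± 0.07. Without replicate 1 of the IL1β group the stromal list lost its call.

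Further lists were called higher under IL1β with the preset correlation of camera and not with an estimated one. Growth factors of angiogenesis and EGFR ligands gave 14 higher and 1 lower of 20 (14 and 1 adjusted over the list alone, median 0.79, camera adjusted p = 5.82e-10, and adjusted p = 0.0678 with an estimated correlation). The integrated stress and unfolded protein response gave 20 and 3 of 27 (21 and 3 adjusted over the list alone, median 0.42, camera adjusted p = 1.15e-08, and adjusted p = 0.103 with an estimated correlation). MAPK phosphatases and Sprouty feedback gave 16 and 0 of 20 (17 and 0 adjusted over the list alone, median 0.64, camera adjusted p = 1.42e-06, and adjusted p = 0.127 with an estimated correlation). Extracellular matrix gave 13 and 2 of 24 (15 and 2 adjusted over the list alone, median 0.31, camera adjusted p = 2.13e-06, and adjusted p = 0.111 with an estimated correlation). Apoptosis regulators gave 14 and 2 of 25 (15 and 2 adjusted over the list alone, median 0.44, camera adjusted p = 2.8e-06, and adjusted p = 0.071 with an estimated correlation). Glycolysis and hypoxia gave 14 and 2 of 28 (16 and 2 adjusted over the list alone, median 0.29, camera adjusted p = 5.01e-05, and adjusted p = 0.28 with an estimated correlation). The p53 targets gave 10 and 5 of 22 (12 and 5 adjusted over the list alone, median 0.35, camera adjusted p = 0.00516, and adjusted p = 0.127 with an estimated correlation). Aryl hydrocarbon receptor targets gave 3 and 0 of 5 (3 and 0 adjusted over the list alone, median 0.38, camera adjusted p = 0.00128, and adjusted p = 0.071 with an estimated correlation). Prostaglandin synthesis and receptors gave 5 and 3 of 16 (7 and 3 adjusted over the list alone, median 0.14, camera adjusted p = 0.00307, and adjusted p = 0.103 with an estimated correlation). TGF-β targets gave 8 and 4 of 19 (8 and 4 adjusted over the list alone, median 0.09, camera adjusted p = 0.0354, and adjusted p = 0.127 with an estimated correlation). After the correction for transcript length and GC content camera no longer called aryl hydrocarbon receptor targets (adjusted p = 0.0935), prostaglandin genes (0.346), TGF-β targets (0.127) or the stromal markers (0.0791), and it called heat shock genes higher (0.00724).

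Lists that camera did not call under IL1β were JNK and MAPK pathway components (10 higher and 5 lower of 25; camera adjusted p = 0.142), YAP and TEAD targets (0.166), heat shock (0.215), cholesterol synthesis (5 and 9 of 24; 0.256) and endothelial markers (0.256). Nor did camera call epithelial and mesenchymal state (7 and 3 of 21; adjusted p = 0.377), epithelial markers (0.377), WNT pathway (0.377), cell cycle (5 and 8 of 37; 0.56) or mitochondrial messenger genes (0 and 0 of 13; 0.565). The same holds for histone genes (camera adjusted p = 0.643), NRF2 targets (0.901), mesothelial markers (0.901) and the oestrogen and progesterone axis (3 and 2 of 14; 0.911). Over all 6 comparisons, the only camera calls that held with an estimated correlation were those of chemokines, NF-κB genes, interferon-stimulated genes, adhesion molecules, AP-1 genes and matrix proteases under IL1β.

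In total 2769 genes were higher and 2360 lower under IL1β (edgeR, adjusted p under 0.05), 679 and 490 of them by at least 2-fold. The balance rested on the scaling: 54% of calls were higher with TMM factors and 25.5% (1623 higher, 4730 lower) with library totals, where the median log2 change of all genes was -0.18. The lower count was 1531 without vehicle replicate 1, and 1393 and 1466 without IL1β replicate 1 or 2.

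**Figure D1:**
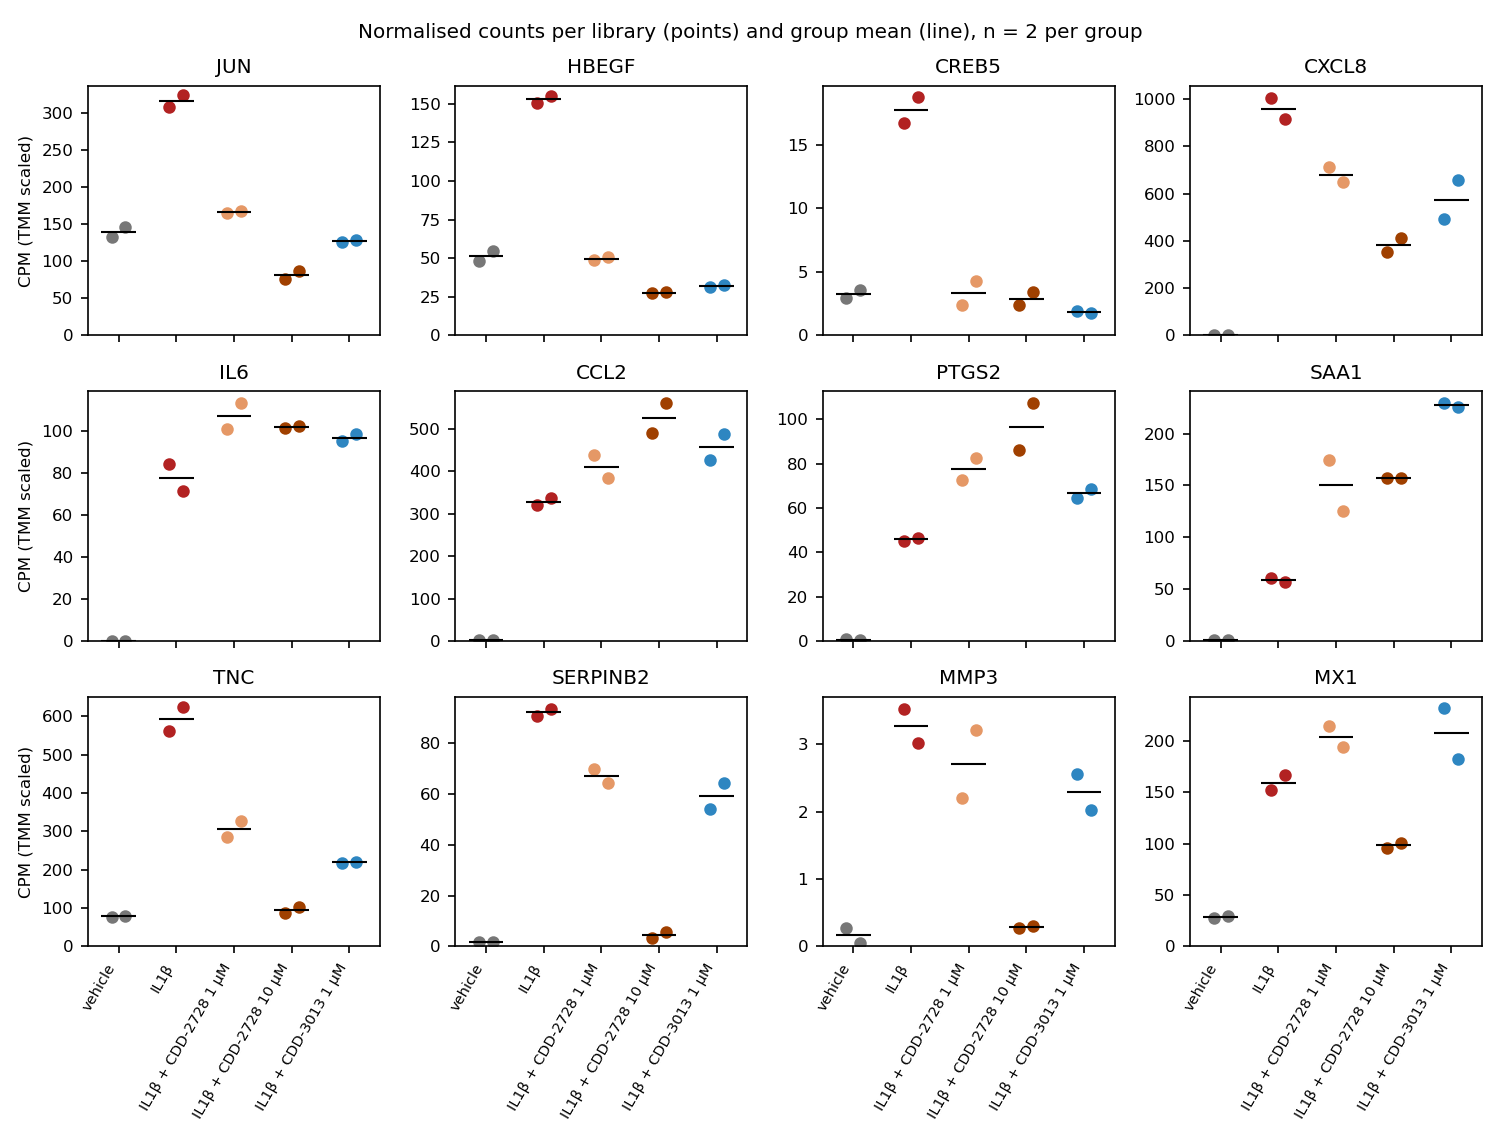
Levels of 12 genes in the 5 groups, in CPM scaled by TMM factors. Each point is a library and each black line a group mean of 2 libraries, and every panel has its own axis from 0. JUN, HBEGF and CREB5 were lower in all 3 inhibitor groups than with IL1β alone, SAA1 was higher in all 3, and SERPINB2 and MMP3 were lowest among the IL1β groups at 10 µM CDD-2728.

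At 1 µM, CDD-2728 lowered a small set of IL1β-raised genes, JUN among them. HBEGF fell by 1.62 ± 0.08 on the log2 scale, to 49.7 ± 1.26 CPM (edgeR, adjusted p = 6.69e-12), CREB5 by 2.42 ± 0.22, to 3.346 ± 1.38 CPM, and DUSP8, a phosphatase of JNK and p38, by 1.76 ± 0.11. JUN fell by 0.92 ± 0.07, to 166.9 ± 2.75 CPM (edgeR, adjusted p = 1.37e-08). FILIP1L fell by 1.31 ± 0.07, the scaffold protein NEDD9 by 1.65 ± 0.22, the growth factors FGF5 and PDGFB by 1.48 ± 0.2 and 1.44 ± 0.11, and the matrix glycoprotein TNC by 0.95 ± 0.08. TDO2, which degrades tryptophan, rose by 2.37 ± 0.21, the acute-phase SAA1 and SAA2 by 1.36 ± 0.12 and 1.4 ± 0.09, and C2CD4A by 1.49 ± 0.15.

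Interferon-stimulated genes gave 19 higher and 0 lower of 37 at 1 µM CDD-2728 (26 and 0 adjusted over the list alone, median log2 change 0.42, camera adjusted p = 2.73e-23, and adjusted p = 0.103 with an estimated correlation). In it IFIT2 rose by 0.94 ± 0.14. IFIT2 was also among the 6 members called higher at 10 µM (0.77), where 11 were called lower. Of the chemokine and cytokine list, CXCL10, an attractant of T cells, rose by 1.27 ± 0.14, and TNFSF10, the death ligand TRAIL, by 1.19 ± 0.15. CXCL10 (0.6) and TNFSF10 (1.5) were higher at 10 µM as well. MAPK phosphatases and Sprouty feedback gave 0 higher and 5 lower of 20 (1 and 7 adjusted over the list alone, median -0.18, camera adjusted p = 9.28e-07, and adjusted p = 0.213 with an estimated correlation). DUSP1 was at -0.69 ± 0.11 and DUSP4 at -0.6 ± 0.09. AP-1 genes gave 0 higher and 4 lower of 16 (1 and 6 adjusted over the list alone, median -0.06, camera adjusted p = 9.97e-05, and adjusted p = 0.103 with an estimated correlation). JUND was at -0.59 ± 0.07. Prostaglandin synthesis and receptors gave 3 higher and 0 lower of 16 (5 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 3.93e-05, and adjusted p = 0.103 with an estimated correlation). They were PTGS2 (0.76 ± 0.1), the phospholipase PLA2G4A (0.77 ± 0.12) and the receptor PTGER4 (0.7 ± 0.1). Stromal markers gave 4 higher and 0 lower of 12 (5 and 0 adjusted over the list alone, median 0.16, camera adjusted p = 6.08e-05, and adjusted p = 0.103 with an estimated correlation). NRF2 targets gave 3 and 0 of 21 (4 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 0.000867, and adjusted p = 0.354 with an estimated correlation). Cell cycle gave 2 and 0 of 37 (7 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 7.57e-05, and adjusted p = 0.213 with an estimated correlation). The integrated stress and unfolded protein response gave 4 and 1 of 27 (11 and 3 adjusted over the list alone, median 0.15, camera adjusted p = 0.00306, and adjusted p = 0.4 with an estimated correlation).

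Chemokines and cytokines gave 8 higher and 1 lower of 26 at 1 µM CDD-2728 (12 and 3 adjusted over the list alone, median 0.23, camera adjusted p = 1.99e-06, and adjusted p = 0.117 with an estimated correlation), a call lost after correction for transcript length and GC content (median 0.12; camera adjusted p = 0.103). CXCL8 was the 1 lower, by 0.5 ± 0.12 (edgeR, adjusted p = 0.0285), and lost its call without any 1 of the 4 libraries and in DESeq2. IL6 rose by 0.46 ± 0.08 and CCL2 by 0.32 ± 0.08, both lost after the correction (edgeR, adjusted p = 0.135 and 0.0908), IL6 also without IL1β replicate 2, and CCL2 without IL1β replicate 1 or 2 or CDD-2728 replicate 1. Called lower were growth factors of angiogenesis and EGFR ligands, with 3 higher and 5 lower of 20 (3 and 6 adjusted over the list alone, median -0.04, camera adjusted p = 8.87e-05, and adjusted p = 0.213 with an estimated correlation). So was extracellular matrix, with 2 and 5 of 24 (3 and 7 adjusted over the list alone, median -0.1, camera adjusted p = 0.0332, and adjusted p = 0.506 with an estimated correlation). Matrix proteases gave 2 and 6 of 27 (3 and 7 adjusted over the list alone, median -0.14, camera adjusted p = 0.0379, and adjusted p = 0.237 with an estimated correlation). These 3 calls were lost after the correction (camera adjusted p = 0.199, 0.506 and 0.276). So were 3 calls towards higher values. Histone genes gave 1 and 0 of 7 (1 and 0 adjusted over the list alone, camera adjusted p = 0.0162, then 0.0708, and adjusted p = 0.294 with an estimated correlation). Aryl hydrocarbon receptor targets gave 2 and 0 of 5 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0283, then 0.103, and adjusted p = 0.213 with an estimated correlation). Heat shock gave 0 and 1 of 16 (2 and 1 adjusted over the list alone, camera adjusted p = 0.0332, then 0.0794, and adjusted p = 0.529 with an estimated correlation), with a median of 0.12. The metalloproteinase inhibitor TIMP3 fell by 0.63 ± 0.08, while MMP1 (0.35 ± 0.13) and MMP3 (-0.28 ± 0.3) did not pass the test.

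The test called 319 genes higher and 404 lower at 1 µM CDD-2728 (edgeR, adjusted p under 0.05), 38 and 24 of them by at least 2-fold. These counts rested on single libraries: 96 and 128 without IL1β replicate 1, 164 and 151 without IL1β replicate 2, 168 and 150 without CDD-2728 replicate 1, and 854 and 632 without CDD-2728 replicate 2.

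At 10 µM, CDD-2728 changed many more genes and took several IL1β-raised genes near or below their vehicle level. JUN fell by 1.96 ± 0.07 on the log2 scale, to 81.64 ± 7.12 CPM, HBEGF by 2.47 ± 0.08, to 27.57 ± 0.569 CPM, and DUSP8 by 3.61 ± 0.14. TNC, 78.39 CPM with vehicle and 592.8 ± 43.2 with IL1β, was at 94.58 ± 10.7, and CREB5 was at 2.905 ± 0.711 CPM. SERPINB2 fell by 4.36 ± 0.16, from 92.1 ± 2.07 to 4.521 ± 1.64 CPM (chr18:63871692-63903890, plus strand; edgeR, adjusted p = 2.75e-15), and stayed above its vehicle level of 1.628 CPM. INHBA, a subunit of activin, fell 4.71-fold. CXCL8 fell by 1.33 ± 0.12, to 382.1 ± 41.5 CPM (edgeR, adjusted p = 2.17e-06), while CCL2 (0.67 ± 0.08), PTGS2 (1.08 ± 0.1), LIF (0.7 ± 0.07) and ICAM1 (0.62 ± 0.06) rose further. Among the genes chosen by size, the largest rises were those of BNIP5 (44.5-fold), C2CD4B (11.9-fold), PPP1R32 (9.43-fold), the Notch ligand DLL4 (8.85-fold) and ATP6AP1L (8.08-fold). BNIP5 had only 5 counts in the IL1β group, so its fold change is imprecise. The receptor tyrosine kinase ROS1 fell 17.6-fold.

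Matrix proteases and inhibitors gave 4 higher and 14 lower of 27 at 10 µM (4 and 14 adjusted over the list alone, median log2 change -0.3, camera adjusted p = 2.44e-06, and adjusted p = 0.175 with an estimated correlation). MMP3 went from 3.27 ± 0.361 to 0.2829 ± 0.0226 CPM, MMP1 fell 2.36-fold and the collagenase MMP13 7.53-fold, and MMP10 was 12.6-fold lower (3.98 to 63.9). Growth factors of angiogenesis and EGFR ligands gave 5 higher and 9 lower of 20 (5 and 10 adjusted over the list alone, median -0.3, camera adjusted p = 6.23e-07, and adjusted p = 0.198 with an estimated correlation). FGF2 fell 2.18-fold and PDGFB 5.58-fold, while the endothelial growth factor VEGFA rose by 0.83 ± 0.08. Extracellular matrix gave 2 higher and 11 lower of 24 (2 and 12 adjusted over the list alone, median -0.13, camera adjusted p = 0.000725, and adjusted p = 0.338 with an estimated correlation). YAP and TEAD targets gave 2 and 11 of 22 (3 and 11 adjusted over the list alone, median -0.24, camera adjusted p = 0.00183, and adjusted p = 0.402 with an estimated correlation), lost after the length and GC correction (camera adjusted p = 0.0772). Cell cycle gave 1 higher and 12 lower of 37 (1 and 12 adjusted over the list alone, median -0.12, camera adjusted p = 0.0494, and adjusted p = 0.449 with an estimated correlation), lost without IL1β replicate 1 or without 10 µM replicate 2.

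The integrated stress and unfolded protein response rose at 10 µM, with 19 higher and 1 lower of 27 (19 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 1.22e-13, and adjusted p = 0.196 with an estimated correlation). CHAC1, which degrades glutathione, rose from 14.73 to 54.65 CPM, and PPP1R15A, a regulator of eIF2α dephosphorylation, by 1 ± 0.09. The p53 targets gave 13 higher and 1 lower of 22 (13 and 1 adjusted over the list alone, median 0.44, camera adjusted p = 0.00051, and adjusted p = 0.198 with an estimated correlation). The stress cytokine GDF15 was at 3.37-fold and the cell cycle inhibitor CDKN1A at 0.54 ± 0.07. Immediate-early and SRF targets gave 11 and 3 of 20 (11 and 3 adjusted over the list alone, median 0.41, camera adjusted p = 0.000725, and adjusted p = 0.338 with an estimated correlation). The nuclear receptor NR4A1 was at 3.4-fold and ZFP36, which destabilizes mRNA, at 2.64-fold. FOS rose by 2.27 ± 0.23, to 10.28 CPM, and JUNB by 1.13 ± 0.1, while the AP-1 list gave 7 higher and 4 lower of 16 and no camera call (adjusted p = 0.561). NF-κB genes gave 12 and 4 of 26 (13 and 4 adjusted over the list alone, median 0.24, camera adjusted p = 0.000725, and adjusted p = 0.338 with an estimated correlation). The NF-κB subunit NFKB2 and the coactivator BCL3 were at 2.05- and 2.18-fold. NRF2 targets gave 8 and 1 of 21 (8 and 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.00877, and adjusted p = 0.449 with an estimated correlation). The heme oxygenase HMOX1 was at 2.75-fold. Glycolysis and hypoxia gave 6 and 4 of 28 (7 and 5 adjusted over the list alone, median 0.06, camera adjusted p = 0.0323, and adjusted p = 0.597 with an estimated correlation), lost after the length and GC correction (camera adjusted p = 0.383), without IL1β replicate 1 or without 10 µM replicate 2. Chemokines (10 higher and 8 lower of 26; camera adjusted p = 0.627) and interferon-stimulated genes (6 and 11 of 37; median -0.18; 0.446) were not called.

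In total 2454 genes were higher and 2504 lower at 10 µM CDD-2728 (edgeR, adjusted p under 0.05), 622 and 259 by at least 2-fold. With library totals the share higher went from 49.5% to 61.7% (3082 higher, 1911 lower). The counts were 1567 higher and 1638 lower without IL1β replicate 1, and 1616 higher without IL1β replicate 2.

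CDD-3013 at 1 µM lowered JUN and a set of IL1β-raised genes. CREB5 fell by 3.24 ± 0.26, to 1.866 ± 0.134 CPM (edgeR, adjusted p = 1.78e-09), HBEGF by 2.25 ± 0.08, to 32.13 ± 0.809 CPM, DUSP8 by 2.51 ± 0.12 and FILIP1L by 1.9 ± 0.07. TNC fell by 1.44 ± 0.08 and JUN by 1.31 ± 0.07, to 128 ± 1.61 CPM (edgeR, adjusted p = 2.23e-11). BACH2, a transcriptional repressor, fell by 1.99 ± 0.22 and NEDD9 by 2.04 ± 0.23. CXCL8 fell by 0.74 ± 0.12, to 573.7 ± 116 CPM. TDO2 rose by 2.77 ± 0.21, SAA1 by 1.95 ± 0.12, to 227.4 ± 2.46 CPM, G0S2 by 1.88 ± 0.21 and the placental growth factor PGF by 1.14 ± 0.11. All these calls held after the length and GC correction.

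Fold changes of CDD-3013 fell with transcript length. Over 8168 genes with mean log2 CPM over 4, the Spearman correlation with transcript length was -0.65, and the median log2 change was 0.38 in the shortest 20% of genes (up to 2322 bases) and -0.3 in the longest 20% (from 6250 bases). The correlation with GC content was 0.45. The correlation with length was -0.43 for 1 µM CDD-2728, -0.13 for 10 µM, 0.09 for IL1β against vehicle, and -0.66 for CDD-3013 against 1 µM CDD-2728. Libraries of 1 group also differed along length, with correlations of the replicate difference of 0.55 (vehicle), 0.16 (IL1β), -0.6 (1 µM CDD-2728), 0.39 (10 µM) and 0.39 (CDD-3013). Ribosomal protein genes held 4.01% and 4.75% of counts in the CDD-3013 libraries, against 2.81% and 2.88% with IL1β alone, 2.96% and 3.46% with vehicle, 3.71% and 3% at 1 µM CDD-2728 and 3.22% and 3.29% at 10 µM. Of 2994 genes higher and 2729 lower with CDD-3013 (edgeR, adjusted p under 0.05; 176 and 276 by at least 2-fold), 1303 (43.5%) and 1453 (53.2%) kept their call after the correction, which called 1929 and 2223 in all. The lower count was 1603 without IL1β replicate 1 and 1775 without CDD-3013 replicate 2, and the share higher was 52.3% with TMM and 39.2% (2285 higher, 3548 lower) with library totals.

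**Figure D2:**
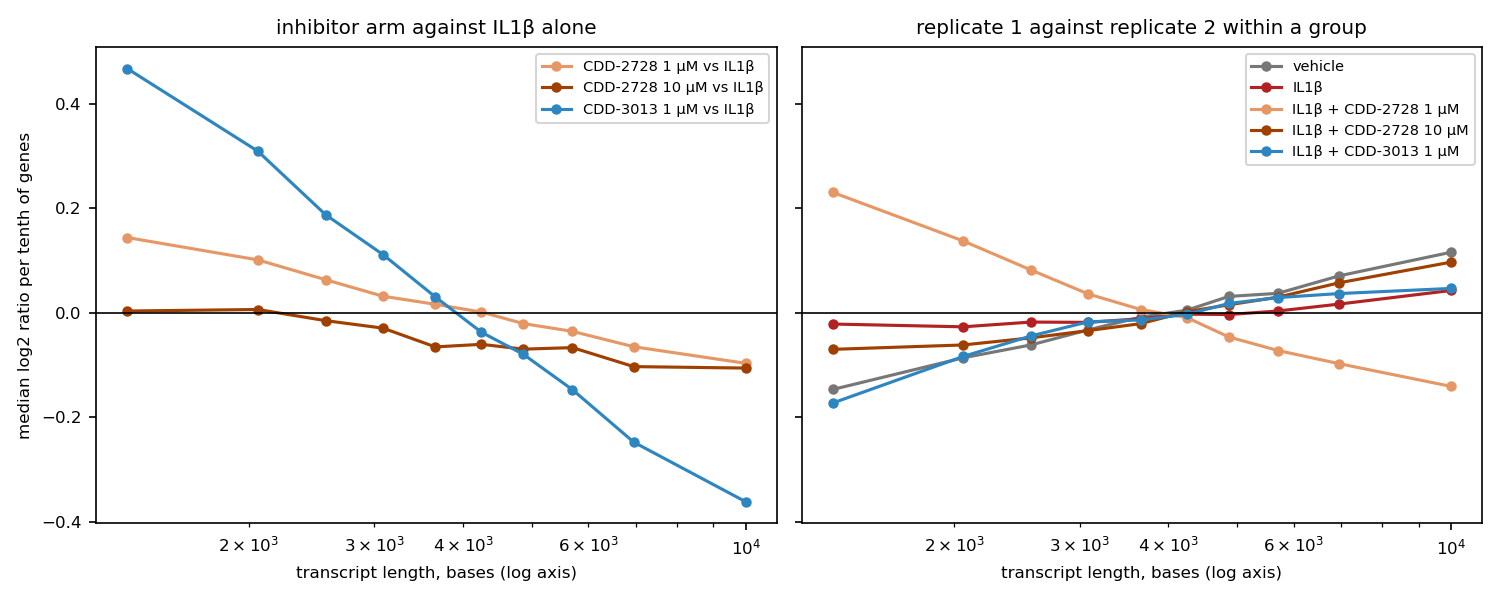
Median log2 ratio in 10 equal groups of genes ordered by transcript length (log axis, bases). The left panel shows the 3 inhibitor arms against IL1β alone and the right panel replicate 1 against 2 within each of the 5 groups. CDD-3013 fell along length (Spearman correlation over genes -0.65), as did the replicate difference of 1 µM CDD-2728 (-0.6).

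Interferon-stimulated genes gave 27 higher and 0 lower of 37 with CDD-3013 (27 and 1 adjusted over the list alone, median 0.61, and 0.43 after the correction, camera adjusted p = 5.03e-10, and adjusted p = 0.369 with an estimated correlation). In it OASL, an antiviral protein, rose by 1.4 ± 0.16. Of the chemokine and cytokine list, CXCL10 rose by 1.39 ± 0.14 and TNFSF10 by 1.38 ± 0.15. MAPK phosphatases and Sprouty feedback gave 2 higher and 7 lower of 20 (2 and 8 adjusted over the list alone, median -0.23, and -0.35 after the correction, camera adjusted p = 0.00295, and adjusted p = 0.369 with an estimated correlation). YAP and TEAD targets gave 2 and 13 of 22 (2 and 16 adjusted over the list alone, median -0.24, and -0.16 after the correction, camera adjusted p = 0.00295, and adjusted p = 0.369 with an estimated correlation). NRF2 targets gave 10 higher and 1 lower of 21 (11 and 2 adjusted over the list alone, median 0.4, and 0.13 after the correction, camera adjusted p = 0.000578, and adjusted p = 0.369 with an estimated correlation). HMOX1 was at 1.07 ± 0.12 and the quinone reductase NQO1 at 0.6 ± 0.08. Glycolysis and hypoxia gave 15 and 2 of 28 (16 and 3 adjusted over the list alone, median 0.25, and 0.13 after the correction, camera adjusted p = 0.000578, and adjusted p = 0.369 with an estimated correlation). The hexokinase HK2 was at 0.73 ± 0.07 and the glucose transporter SLC2A3 at 0.75 ± 0.08. The integrated stress response gave 18 and 4 of 27 (18 and 4 adjusted over the list alone, median 0.26, and 0.11 after the correction, camera adjusted p = 0.000837, and adjusted p = 0.369 with an estimated correlation).

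Stromal markers gave 5 higher and 1 lower of 12 with CDD-3013 (7 and 1 adjusted over the list alone, median 0.33, and 0.31 after the correction, camera adjusted p = 0.00295, and adjusted p = 0.369 with an estimated correlation). The proteoglycan DCN was at 0.74 ± 0.09 and HAND2 at 1.01 ± 0.1. Cell cycle gave 17 and 3 of 37 (19 and 3 adjusted over the list alone, median 0.18, and 0.09 after the correction, with 9 higher and 4 lower, camera adjusted p = 0.00902, and adjusted p = 0.369 with an estimated correlation). The replication helicase subunit MCM2 was at 0.48 ± 0.06. Prostaglandin synthesis and receptors gave 6 and 1 of 16 (6 and 1 adjusted over the list alone, median 0.28 with and without the correction, camera adjusted p = 0.0308, and adjusted p = 0.369 with an estimated correlation). Other list calls were lost after the length and GC correction. Chemokines gave 13 higher and 3 lower of 26 (13 and 3 adjusted over the list alone, median 0.31, and 0.05 after the correction, camera adjusted p = 0.00414, then 0.705). IL6 (0.31 ± 0.08, then 0.01), CCL2 (0.48 ± 0.08, then 0.09) and MMP1 (0.5 ± 0.13, then 0.3) lost their calls as well, while PTGS2 (0.54 ± 0.1, then 0.75) kept it. CXCL1 (0.31, then -0.11) and NFKBIA (0.24, then -0.19) changed direction. Extracellular matrix gave 3 higher and 10 lower of 24 (3 and 10 adjusted over the list alone, median -0.12, camera adjusted p = 0.00591, then 0.511). Adhesion molecules gave 5 and 9 of 30 (5 and 10 adjusted over the list alone, median -0.13, camera adjusted p = 0.0148, then 0.511), with the integrin subunit ITGA2 at -0.97 ± 0.09. Histone genes gave 3 and 0 of 7 (3 and 0 adjusted over the list alone, median 0.38, camera adjusted p = 0.0207, then 0.562). Growth factors of angiogenesis and EGFR ligands gave 6 and 8 of 20 (6 and 8 adjusted over the list alone), with a median of 0.03, a mean of -0.14 and a test towards lower values (camera adjusted p = 0.0195, then 0.511). Adjusted p was 0.369 with an estimated correlation for each of these 5 lists.

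**Figure D3:**
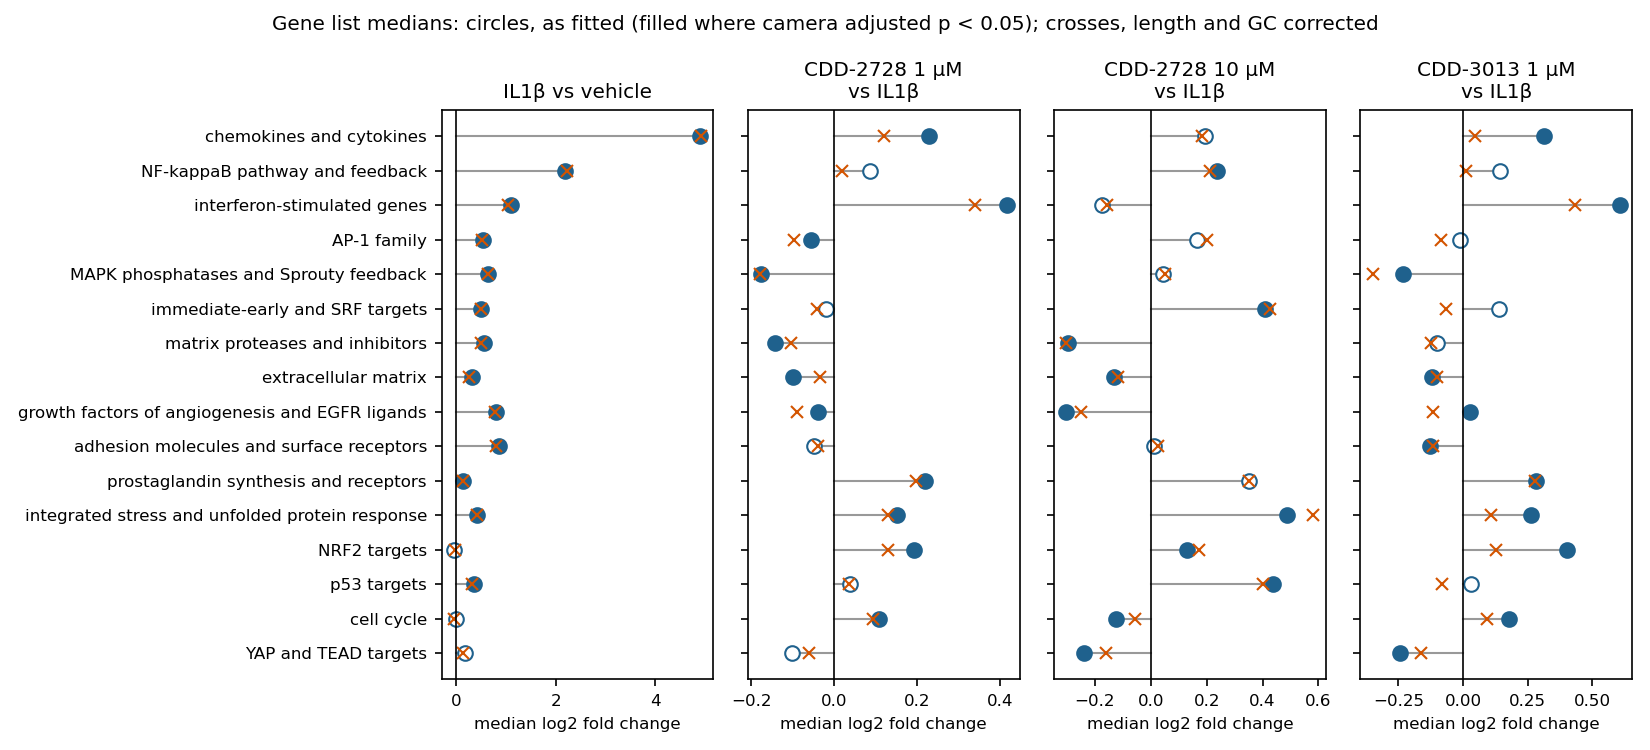
Median log2 fold change of 16 gene lists in IL1β against vehicle and the 3 inhibitor arms against IL1β alone. Circles are values as fitted, filled where the camera adjusted p was under 0.05 with the preset correlation, and crosses are values corrected for transcript length and GC content, and the scales differ between panels. Interferon-stimulated genes were higher at 1 µM of both compounds (0.42 and 0.61) and not at 10 µM CDD-2728 (-0.18).

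JUN was lower at 10 than at 1 µM CDD-2728, by 1.03 (95% interval -1.18 to -0.88), and SERPINB2 by 3.91 ± 0.16 (edgeR, adjusted p = 1.67e-13). CXCL8 was lower by 0.83 (-1.08 to -0.58), and the test called MMP1 (-1.59) and MMP3 (-3.22) lower. TXNIP, an inhibitor of thioredoxin, fell from 28.67 to 4.839 CPM and the cytokine IL24 by 2.22 ± 0.38. FOS (1.75 ± 0.21), CHAC1 (1.34 ± 0.13), the phosphatase DUSP5 (1.4 ± 0.14) and SPRY4, a Sprouty inhibitor of receptor kinase signalling (1.61 ± 0.14), rose. CREB5 (-0.2; -0.75 to 0.35), IL6 (-0.07; -0.24 to 0.1) and TNFAIP3 (-0.1; -0.25 to 0.05) did not differ by the test. MMP10 was 6.97-fold lower (2.07 to 36.6).

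Interferon-stimulated genes gave 1 higher and 26 lower of 37 at 10 against 1 µM (1 and 27 adjusted over the list alone, median -0.53, camera adjusted p = 4.19e-13, and adjusted p = 0.17 with an estimated correlation). The 1 higher, named after its value was seen, was the transcription factor IRF1 (1.2). Cell cycle gave 0 and 22 of 37 (1 and 26 adjusted over the list alone, median -0.24, camera adjusted p = 2.84e-07, and adjusted p = 0.14 with an estimated correlation). Matrix proteases gave 2 and 12 of 27 (5 and 12 adjusted over the list alone, median -0.23, camera adjusted p = 2.82e-05, and adjusted p = 0.14 with an estimated correlation). The integrated stress response gave 19 and 2 of 27 (19 and 2 adjusted over the list alone, median 0.41, camera adjusted p = 1.1e-11, and adjusted p = 0.14 with an estimated correlation). Immediate-early and SRF targets gave 13 and 1 of 20 (13 and 1 adjusted over the list alone, median 0.52, camera adjusted p = 1.07e-06, and adjusted p = 0.14 with an estimated correlation). The p53 targets gave 10 and 0 of 22 (11 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 2.82e-05, and adjusted p = 0.14 with an estimated correlation). MAPK phosphatases gave 7 and 1 of 20 (8 and 1 adjusted over the list alone, median 0.27, camera adjusted p = 5.18e-05, and adjusted p = 0.25 with an estimated correlation). NF-κB genes gave 12 and 3 of 26 (13 and 3 adjusted over the list alone, median 0.19, camera adjusted p = 0.00136, and adjusted p = 0.25 with an estimated correlation). AP-1 genes gave 9 and 1 of 16 (9 and 2 adjusted over the list alone, median 0.3, camera adjusted p = 0.00148, and adjusted p = 0.14 with an estimated correlation). Growth factors of angiogenesis and EGFR ligands gave 4 and 10 of 20 (5 and 11 adjusted over the list alone, median -0.48, camera adjusted p = 0.000373, and adjusted p = 0.25 with an estimated correlation). Calls towards lower values also fell on extracellular matrix (2 and 7 of 24, 3 and 7 adjusted over the list alone, median -0.05, camera adjusted p = 0.00701, and adjusted p = 0.373 with an estimated correlation) and YAP and TEAD targets (2 and 7 of 22, 3 and 9 adjusted over the list alone, median -0.14, camera adjusted p = 0.0112, and adjusted p = 0.411 with an estimated correlation). Both were lost without 1 µM replicate 2. Cholesterol synthesis gave 1 and 10 of 24 (2 and 10 adjusted over the list alone, median -0.13, camera adjusted p = 0.0137, and adjusted p = 0.595 with an estimated correlation), lost without 10 µM replicate 2. Chemokines gave 5 and 9 of 26 (6 and 11 adjusted over the list alone, median -0.08, camera adjusted p = 0.0193, and adjusted p = 0.346 with an estimated correlation), lost after the length and GC correction (camera adjusted p = 0.273) and without 10 µM replicate 1. Aryl hydrocarbon receptor targets gave 1 and 2 of 5 (1 and 2 adjusted over the list alone), with a median of 0.03, a mean of -0.19 and a test towards lower values (camera adjusted p = 0.0461, and adjusted p = 0.25 with an estimated correlation). The WNT pathway gave 1 and 6 of 17 (1 and 6 adjusted over the list alone), with a median of 0.02, a mean of -0.11 and a test towards lower values (camera adjusted p = 0.0461, and adjusted p = 0.232 with an estimated correlation). The calls of these 2 lists were lost after the correction.

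In total 2093 genes were higher and 2169 lower (edgeR, adjusted p under 0.05), 530 and 145 by at least 2-fold. The share higher was 49.1% with TMM and 67% (2826 higher, 1389 lower) with library totals. The higher count was 1389 without 1 µM replicate 1, and the counts were 1330 and 1338 without 10 µM replicate 1, and 1329 and 1393 without 10 µM replicate 2.

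Against each other at 1 µM, CDD-3013 gave lower levels than CDD-2728 for several genes that both lowered. JUN was lower by 0.38 (95% interval -0.53 to -0.23, edgeR adjusted p = 0.00166), and the difference was -0.51 after the length and GC correction. HBEGF was lower by 0.63 (-0.81 to -0.45; corrected -0.78) and DUSP8 by 0.75 (-1.02 to -0.47; corrected -0.88). FILIP1L was lower by 0.59 (-0.73 to -0.44; corrected -0.49) and TNC by 0.48 (-0.65 to -0.32; corrected -0.4). No difference passed the test for CXCL8 (-0.25; -0.5 to 0.01), IL6 (-0.14; -0.31 to 0.03), CCL2 (0.16; -0.01 to 0.32), PTGS2 (-0.22; -0.42 to -0.01), MMP3 (-0.23; -0.89 to 0.43) or CREB5 (-0.82; -1.44 to -0.21). SAA1 was higher with CDD-3013 by 0.6 (0.36 to 0.83), a call lost after the correction (0.24; edgeR, adjusted p = 0.112). CDD-3013 was not used at 10 µM, so the compounds can be compared at 1 µM only.

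As fitted, 1550 genes were higher and 1261 lower with CDD-3013 than with 1 µM CDD-2728 (edgeR, adjusted p under 0.05), 21 and 34 by at least 2-fold. After the length and GC correction 427 were higher and 264 lower, with 224 (14.5%) and 176 (14%) of the calls kept. The counts were 318 and 338 without CDD-2728 replicate 2, 501 and 450 without CDD-3013 replicate 2, and the lower count 815 without CDD-3013 replicate 1. The share higher was 55.1% with TMM and 34.5% (1034 higher, 1965 lower) with library totals. The inhibitory receptor LAG3 (1.17 ± 0.37) was the highest of the genes chosen by size and the zinc finger gene ZNF117 (-1.3 ± 0.32) the lowest, and both lost their calls after the correction. Glycolysis and hypoxia, with 9 higher and 0 lower of 28 (10 and 0 adjusted over the list alone, median 0.2, camera adjusted p = 0.000436, and adjusted p = 0.699 with an estimated correlation), kept its call after the correction (camera adjusted p = 0.00279) with a median of 0.1 and 4 higher genes. The other list calls did not. Adhesion molecules gave 0 higher and 7 lower of 30 (0 and 7 adjusted over the list alone, median -0.13, camera adjusted p = 0.012, then 0.643). YAP and TEAD targets gave 1 and 8 of 22 (1 and 8 adjusted over the list alone, median -0.15, camera adjusted p = 0.012, then 0.0578). The integrated stress response gave 9 and 2 of 27 (10 and 2 adjusted over the list alone, median 0.17, camera adjusted p = 0.0216, then 0.66). NRF2 targets gave 8 and 1 of 21 (9 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.0216, then 0.419). Extracellular matrix gave 1 and 6 of 24 (1 and 6 adjusted over the list alone, median -0.11, camera adjusted p = 0.0482, then 0.799). Each of these 5 had adjusted p = 0.699 with an estimated correlation. Without CDD-2728 replicate 2 all 5 lost their calls as well. Chemokines gave 0 calls of 26 (camera adjusted p = 0.816).

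Of the 679 genes that IL1β raised at least 2-fold, most stayed raised with either compound. The median share of the log2 response left was 1.006 ± 0.016 at 1 µM CDD-2728, 0.921 ± 0.018 at 10 µM and 1.001 ± 0.002 with CDD-3013 (mean ± SD of 2 libraries). Called back towards vehicle were 66 (9.7%), 221 (32.5%) and 174 (25.6%), among them JUN and HBEGF in all 3, and 108 (15.9%), 171 (25.2%) and 180 (26.5%) were called further away, among them PTGS2 and SAA1. Of the 490 genes that IL1β lowered at least 2-fold, 23 (4.7%), 217 (44.3%) and 83 (16.9%) were called back towards vehicle, with 0.819 ± 0.013, 0.501 ± 0.013 and 0.781 ± 0.001 of the response left. Choosing genes by their response to the same IL1β libraries can itself lower these shares. Arms simulated with no effect gave medians, taken from the fit, of 0.986 for raised and 0.913, 0.912 and 0.917 for lowered genes. Observed medians taken from the fit were 1.003, 0.92 and 0.998 for raised and 0.808, 0.501 and 0.796 for lowered genes. The simulations chose more genes than the data (means of 806.65 raised and 707.4 lowered), so the size of this effect in the data may differ.

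**Figure D4:**
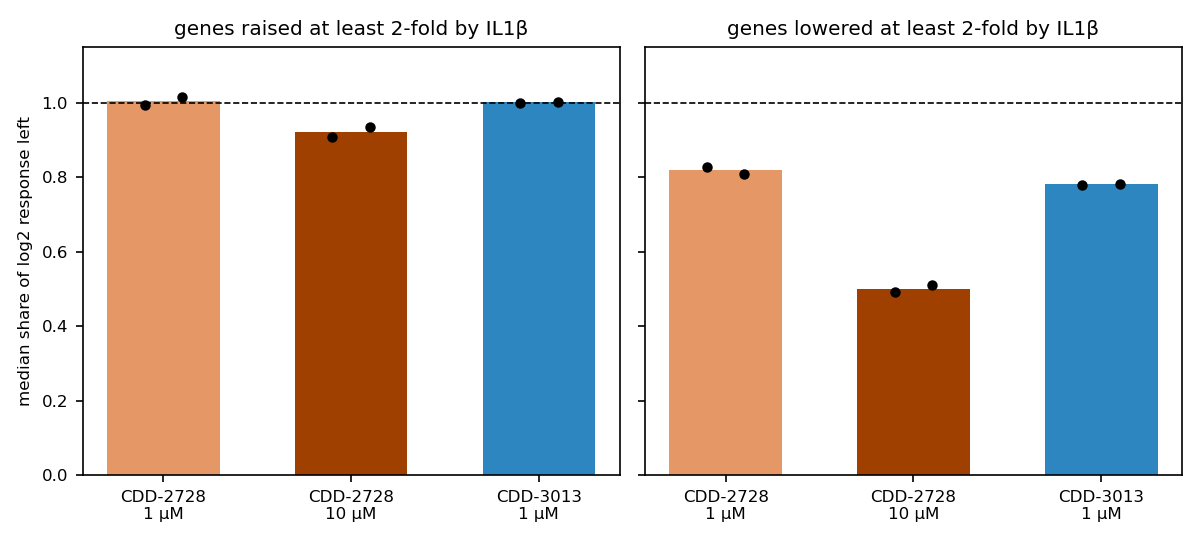
Median share of the log2 response to IL1β left with each inhibitor, for genes that IL1β raised (left) or lowered (right) by at least 2-fold. Bars are means of 2 libraries, points are libraries, and the dashed line at 1 is the full response. The lowest value was 0.501 for lowered genes at 10 µM CDD-2728.

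All 3 inhibitor arms shared 299 lower and 209 higher genes against IL1β alone, of which 63 and 59 by at least 1.5-fold in each arm. The following members were named after their values were seen, with log2 changes for 1 µM CDD-2728, 10 µM CDD-2728 and CDD-3013. They were the growth factor TGFB2 (-0.73, -1.73, -1.08), the osteogenic factor RUNX2 (-0.77, -1.61, -1.32) and the metalloproteinase PAPPA (-0.88, -1.75, -1.48). Others were the signalling adaptor TRAF1 (-0.93, -1.85, -1.41), the cell cycle kinase CDK6 (-0.72, -1.37, -1.41) and the transcription factor PAX8 (-0.84, -0.8, -1). The 59 higher genes included SAA1, SAA2 and TDO2. Also in this set, named after their values were seen (10 µM CDD-2728 and CDD-3013), were the chitinase-like CHI3L1 (1.33 and 1.45) and CHI3L2 (2.38 and 3.07), SOCS3, a feedback inhibitor of cytokine signalling (2.07 and 1.24), and ID1, an inhibitor of DNA binding (1.75 and 1.53).

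The 3 arms were compared with the same 2 IL1β libraries, which raises any overlap of calls. Overlaps exceeded those of independent lists (in parentheses). They were 228 genes higher (49.7) and 315 lower (64.3) in the CDD-2728 arms, 296 (60.7) and 376 (70) in the 1 µM arms, and 892 (466.8) and 1128 (434.1) in the 10 µM and CDD-3013 arms. Part of this excess may come from the shared libraries. The correlation of log2 changes was 0.44, 0.624 and 0.413 for these pairs, against 0.509, 0.499 and 0.499 in simulations with no effect, and the covariance was 0.1083, 0.1389 and 0.1378, against 0.039, 0.039 and 0.038. Without IL1β replicate 1 the genes shared by all 3 arms numbered 66 higher and 114 lower. They numbered, without IL1β replicate 2 112 and 122, without 1 µM CDD-2728 replicate 1 119 and 124, and without its replicate 2 341 higher.

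Transcripts of the JNK genes themselves were present: MAPK8 was at 29.77, 33.89, 33.07, 33.9 and 26.48 CPM and MAPK9 at 69.35, 68.8, 63.14, 57.14 and 58.39 CPM in vehicle, IL1β, 1 µM CDD-2728, 10 µM CDD-2728 and CDD-3013. MAPK10 was at 0.954 to 2.524 CPM. MAPK8 fell by 0.35 ± 0.1 with CDD-3013 (edgeR, adjusted p = 0.0058) and was lower by 0.32 ± 0.1 than with 1 µM CDD-2728 (0.0232), and both calls were lost after the length and GC correction (-0.06 and -0.07; edgeR, adjusted p = 0.681 and 0.737). MAPK9 fell by 0.27 ± 0.08 at 10 µM CDD-2728 (edgeR, adjusted p = 0.0132, and 0.035 after the correction), a call lost without any 1 of the 4 libraries. With CDD-3013 it fell by 0.24 ± 0.08 (edgeR, adjusted p = 0.0243), lost after the correction (-0.1; 0.3) and in DESeq2 (0.0513). MAPK10 fell by 1.01 ± 0.39 under IL1β (edgeR, adjusted p = 0.0417), lost in DESeq2 (0.0995) and without either vehicle library or IL1β replicate 2. It rose by 1.38 ± 0.38 at 10 µM CDD-2728 (edgeR, adjusted p = 0.00622, and 0.00218 after the correction), lost without IL1β replicate 2 or 10 µM replicate 1. Between the doses it was higher at 10 µM by 1.14 ± 0.37 (edgeR, adjusted p = 0.0213), lost in DESeq2 (0.0594).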

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

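The tests of libraries of a group differing along transcript length, and of interferon-stimulated genes measured against 10 µM CDD-2728 or against single IL1β libraries, were chosen only after the result was seen. Each result in the next paragraph was noted because the 2 doses of CDD-2728 moved it in opposite directions against IL1β alone, each dose passing the test, with a difference between doses that also passed it.

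The log2 difference between 10 and 1 µM of CDD-2728 (with the changes at 1 and at 10 µM against IL1β) was -4.22 for the collagenase MMP13 (1.31 and -2.91), -1.73 for the prostaglandin receptor PTGER4 (0.7 and -1.03), -0.98 for the chemokine CCL5 (0.53 and -0.46) and -0.65 for the chemokine CXCL1 (0.3 and -0.35). It was -1.42 for MX2 (0.91 and -0.51), -1.05 for MX1 (0.36 and -0.7) and -1.13 for IFIT1 (0.72 and -0.41), all interferon-stimulated. It was 0.73 for the early response gene IER3 (-0.39 and 0.35) and -0.43 for the mitotic cyclin CCNB1 (0.24 and -0.18), and the median of the cell cycle list differed by -0.242 (0.107 and -0.124). The edgeR test of the difference gave adjusted p from 1.32e-10 (PTGER4) to 8.62e-05 (CCNB1), and camera 2.84e-07 for the list. With an estimated correlation the camera calls of the list were lost (adjusted p = 0.213 at 1 µM, 0.449 at 10 µM and 0.14 between doses), and its call at 10 µM (0.0494) was also lost without IL1β replicate 1 or 10 µM replicate 2; at 1 µM the calls of CXCL1 and CCNB1 were lost without IL1β replicate 1 or 2 or CDD-2728 replicate 1, and that of MMP13 without IL1β replicate 2.

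Genes lower by at least 1.5-fold in all 3 inhibitor arms numbered 63. After the correction 59 of them (93.7%) were still called lower in all 3 arms. A smooth length and GC trend of the form that the correction removes thus did not account for most of the set. Genes chosen at 1.5-fold were little open to that trend. Median log2 changes in the longest of the 10 length groups were -0.0965 (1 µM CDD-2728), -0.1056 (10 µM) and -0.3612 (CDD-3013). Library differences of another form were not tested in this way. A chance high value of 1 IL1β library alone was excluded. Of 50 genes chosen against IL1β library 1, 96% were lower in all 3 arms against library 2. Of 40 chosen the other way round, 100% were. A high value common to both IL1β libraries would pass this test, so it stays open. A response to the inhibitors themselves is a hypothesis that may also account for the shared set. No arm received an inhibitor without IL1β, so whether the genes fall without the cytokine was not tested.

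The fold changes of CDD-3013 fell with transcript length. Replicates of 1 group differed along length by a correlation of up to 0.6, so libraries or RNA that differ in quality could give at least part of the trend, though medians of the shortest and longest 20% of genes were 0.18 and -0.12 in that replicate difference and 0.38 and -0.3 with CDD-3013. Slower transcription through genes that are long in the genome could also take part: given transcript length and GC content, the partial correlation with genomic span was -0.21, just past a bound of -0.2 set beforehand. Within groups that partial correlation was -0.14 to 0.13, and given span and GC content transcript length kept -0.48. Neither explanation was excluded.

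Interferon-stimulated genes were higher at 1 µM of both compounds, with 19 and 27 of 37 called (camera adjusted p = 2.73e-23 and 5.03e-10, and adjusted p = 0.103 and 0.369 with an estimated correlation). The correction for transcript length and GC content took the list medians from 0.42 and 0.61 to 0.34 and 0.43, with 17 and 23 members still called higher. A trend of the form it removes was thus excluded as the only source, but may give part of the rise. The shared IL1β libraries cannot be told apart from a change in the 1 µM arms. Measured against 10 µM CDD-2728 the medians were 0.53 and 0.74, but 6 members were higher and 11 lower in that arm itself, so these values exclude nothing. Against IL1β library 1 alone the medians were 0.45 and 0.65 and against library 2 they were 0.36 and 0.54, and since genes of the list vary together (estimated correlation 0.253), chance low values in both libraries stay open.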

How the results depend on the processing

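The length and GC correction, with and without the replicate block, was added after the data were seen, and all other alternatives were written before. Where no reason is given, the cause was not tested. Main gene counts stayed within 1.5 times under relative log expression factors, DESeq2 and the stricter filter. Of the named gene results, 718 kept direction and side of the threshold in DESeq2 and 23 lost their call, 743 and 1 with relative log expression factors, and 674 and 50 with the length and GC correction. Of the list results, 192 stayed with relative log expression factors, 186 with library totals, 162 with the stricter filter and 165 with the correction, while an estimated correlation ended 74 calls and left 118 as they were. With 2 libraries per group and 16312600 to 19479416 counts, changes under 1.5-fold are often missed (42% called at 1.3-fold and 76% at 1.5-fold in simulated data). The changed genes of those data did not include genes of the lowest levels. Genes of a few counts give ratios with wide intervals.

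Library totals gave 1623 genes higher and 4730 lower for IL1β against vehicle (main 2769 and 2360), 1389 lower for 10 against 1 µM CDD-2728 (2169) and 1965 lower for CDD-3013 against CDD-2728 (1261). No filter gave 551 higher at 1 µM CDD-2728 (319). The length and GC correction gave 617 lower at 1 µM CDD-2728 (404), 1929 higher with CDD-3013 (2994), and 427 higher and 264 lower for CDD-3013 against CDD-2728 (1550 and 1261). Only the 4 libraries compared gave 945 higher in that last comparison, with fewer libraries to estimate the spread. The correction reversed CSF3 (0.18 to -0.26), CXCL1 (0.31 to -0.11), H2BC12 (0.61 to -0.04) and NFKBIA (0.24 to -0.19) with CDD-3013, and IL6ST (-0.3 to 0.05) and SDF2L1 (0.41 to -0.09) in CDD-3013 against CDD-2728.

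A replicate block was fitted although the numbers did not pair the samples: of 10 pairs of groups, 5 had a correlation of deviations over 0.1, with values from -0.53 to 0.34. The replicate block gave 2686 and 2249 genes higher and lower for IL1β, 287 and 346 for 1 µM CDD-2728, 2356 and 2420 for 10 µM, 2906 and 2621 for CDD-3013, 1987 and 2049 between doses and 1420 and 1174 between compounds. With the replicate block the length and GC correction gave 1885 higher with CDD-3013, and 385 higher and 231 lower between compounds. The median share of the raised response left with CDD-3013 was 0.996 with the replicate block.

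The median share of the IL1β-raised response left was 1.003, 0.92 and 0.998 for 1 µM CDD-2728, 10 µM CDD-2728 and CDD-3013. With no size minimum it was 0.934, 0.678 and 0.89, with a 4-fold minimum 1.04, 0.976 and 1.06, and with genes chosen on IL1β library 2 and measured against library 1 1.025, 0.966 and 1.03. Chosen on library 1 and measured against library 2 it was 0.947 at 10 µM and 1.015 with CDD-3013, with library totals 0.953 and 0.975, with the stricter filter 0.966 and 1.002, and with the correction 0.942 and 0.977. Relative log expression factors gave 0.996 with CDD-3013.

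Leaving out each library, with the lone library of a group assumed to vary like the other groups, gave these ranges. For IL1β, 1393 (without IL1β 1) to 1624 (vehicle 2) lower. For 1 µM CDD-2728, 96 (IL1β 1) to 854 (its replicate 2) higher and 128 to 632 lower, for the same libraries. For 10 µM, 1567 (IL1β 1) to 1816 (its replicate 1) higher and 1638 to 1788 lower, likewise. For CDD-3013, 1603 (IL1β 1) to 2071 (its replicate 1) lower. Between doses, 1329 (10 µM 2) to 1828 (1 µM 2) higher and 1338 (10 µM 1) to 2202 (1 µM 2) lower. Between compounds, 318 and 338 (CDD-2728 2) to 1882 and 1425 (CDD-2728 1). Shared by all 3 arms, 66 (IL1β 1) to 341 (1 µM 2) higher and 114 to 392 lower, for the same libraries. The share left ran from 0.897 (IL1β 2) to 0.935 (vehicle 2) at 10 µM and 0.985 (vehicle 1) to 1.014 (vehicle 2) with CDD-3013. Of named gene results, 2711 stayed and 248 lost their call, and of list results 717 and 32.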
